A study of Mus musculus with 3 samples.

How the data were processed

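Per the labels, mouse SCLC line 3 was infected with a lentiviral CRISPR vector for which no guide is named, or with the vector carrying guide sg1 or sg2 against Kdm1a, and RNA was sequenced with paired-end reads. The groups were the control vector (n = 1) and the Kdm1a knock-out (n = 2, 1 per guide), read from the sample titles. The authors deposited a table of 24523 genes with raw read counts per gene and library, and per the submitters' processing notes Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and the mm10 build were used. Their settings, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that share reads with near-identical copies, or with an overlapping or antisense gene, are therefore uncertain. The same deposited table gives RPKM, reads scaled to gene length and library size, which per the file headers stands beside the counts. Between a guide and the control, RPKM over count differed by the same factor for every gene with counts in both libraries. This gave depth ratios to the control of 1.03 for sg1 and 1.18 for sg2. The authors also deposited lists of up and down genes with their RPKM values. Per the file headers, the down list also gives the fold change of each guide over the control. Those deposited fold changes were not used here.

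The count totals were 43424212 (control), 44667861 (sg1) and 51066078 (sg2), and 16841, 17487 and 17461 genes had at least 1 count. Mitochondrial genes took 2.84%, 2.67% and 2.70% of the counts, and the 100 most abundant genes 14.7%, 14.5% and 15.1%. A count of 0 allows up to 3 counts, which is 0.0692 CPM in the control; this limit is per library and was used for all lower bounds of folds. The bounds and the 95% exact counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. For control counts of 1 to 3 the pooled ratio of both guides is given with its interval.

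Differential expression was tested on the counts as deposited with edgeR 4.0.16 (R 4.3.3), using TMM factors, filterByExpr on the group and the quasi-likelihood F test on the group, with Benjamini-Hochberg adjustment over the 15936 genes kept; 8587 genes were not tested. The spread came from the 2 guides (1 residual degree of freedom, moderated over genes with 11.5 prior degrees of freedom; common coefficient of variation 0.387), and the lone control was assumed to vary likewise. The SE of a log2 fold change is its size over the square root of F. CPM are counts scaled to the effective library size, and folds are ratios of mean CPM. Lower bounds of folds also use the mean CPM of both guides, so a single guide can lie below them. Per-guide log2 fold changes used a prior count of 2 and are descriptive. Gene lists, 21 in number, were tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists, with an estimated correlation and the rotation test fry as alternatives. Each list's median per guide was also set against 10000 random lists matched on mean expression: the 7 lists of mesenchymal, non-neuroendocrine, YAP/TAZ, TGF-beta, MHC class I, interferon and fibroblast genes lay at a percentile of 100 and the neuroendocrine and synapse lists at 0 with both guides.

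Design, alternatives, lists and the rule for named genes were fixed before the data were examined. The rule takes Kdm1a, then the 12 higher and 12 lower genes that passed edgeR, lay at least 1.5-fold on the same side with both guides and had the largest smaller-of-the-guides log2 fold change, without predicted genes or genes under 2 CPM on average. It then takes 2 to 4 members per list with the largest fold change among those that passed, or the 2 largest where none passed. Between the guides it takes the 5 genes most higher with sg1 and with sg2 at 10 CPM or more on average. Genes named outside the rule are marked as such, and some genes that the rule takes are not reported here.

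The alternatives were DESeq2 1.42.0 size factors and upper-quartile factors, no filter and a mean count of at least 50, the DESeq2 Wald test, limma-voom, limma-trend on log2(RPKM + 1), prior counts of 0.5 and 10, library totals alone, log2(RPKM + 1) and log2(RPKM + 0.1), a fold threshold of 2, and each guide left out. A loess correction for gene length, with the length implied by counts over RPKM, and a fit without chromosome 15 were added after the data were seen. Leaving out a guide leaves 1 library against 1, which gives a fold change without a test. Positions are those of GRCm38, the assembly of mm10, matched by Entrez identifier for 24418 genes. The scripts were tested on simulated data: with 200 changed genes among 15936 and 5 runs, 7.78% of calls were false. Of 200 unchanged random lists, 5.5% had p under 0.05 with camera. The simulated genes were drawn independently, so this does not check camera's p-values for lists whose members are correlated. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for reading and drawing.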

Results

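Transcript profiles of a mouse small cell lung cancer (SCLC) line, referred to by the submitters as line 3, were compared with and without a knock-out of Kdm1a. SCLC is a lung tumour whose cells commonly carry neuroendocrine markers, and Kdm1a encodes LSD1, a demethylase of histone H3 lysines that acts with CoREST corepressors. Cells were infected with a lentiviral CRISPR vector for which the labels name no guide (control vector, n = 1 library) or with the same vector carrying 1 of 2 guides against Kdm1a, sg1 or sg2 (Kdm1a knock-out, n = 2 libraries, 1 per guide), and were selected with puromycin for at least 1 week. The deposited count table held 24523 genes, with 43424212 counts in the control, 44667861 in sg1 and 51066078 in sg2. The control was not replicated and each guide was sequenced once, so means ± SD below are over the 2 guides (n = 2) and control values carry no SD. Nothing in the labels places the guides in separate cultures beyond their separate infections. The p-values therefore rest on the spread between these 2 libraries, largely moderated over genes, with the lone control assumed to vary likewise. With 1 library per guide, that spread cannot be split into differences between guides and between libraries.

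The level of the targeted gene was examined first, as a check of the labels. Kdm1a (NM_001347221; GRCm38 chromosome 4, 136550533 to 136602787) had 11468 counts in the control, 3950 with sg1 and 5716 with sg2. Its level was 264 CPM (counts scaled to library size) in the control and 100.3 ± 18.0 CPM in the knock-out. The sg1 library held 0.331 of the control level (95% counting interval 0.319 to 0.343) and the sg2 library 0.428 (0.414 to 0.441). The log2 fold change was -1.40 (SE 0.404), which missed the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0537). Both libraries labelled as knock-out thus held less Kdm1a mRNA than the control by more than counting error, although an edited transcript need not be lost and the mRNA does not measure the protein. The call was close to the threshold and passed it under 4 of 8 other analyses, with adjusted p from 0.0166 to 0.127.

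The question of which genes differed between knock-out and control cells was then addressed genome-wide. Genes of mesenchymal cells and of the extracellular matrix that gave no count in the control were abundant with both guides. Vim, the intermediate filament of mesenchymal cells (chromosome 2, 13574311 to 13582826), had 0 counts in the control, 11713 with sg1 and 32362 with sg2. Its knock-out level of 450 ± 269 CPM was at least 6501-fold above the 3-count limit of the control, 0.0692 CPM. Acta2, smooth muscle actin, was at least 3782-fold higher (262 ± 158 CPM), Prrx1, a homeobox factor of mesenchyme, at least 2660-fold (184 ± 56.9 CPM), and Igfbp4, which binds insulin-like growth factors, at least 2291-fold (158 ± 7.49 CPM). The receptor tyrosine kinase Axl was at least 2239-fold higher (155 ± 12.3 CPM) and the matrix proteins Ltbp2, Ccdc80 and Tnc at least 1629-, 1620- and 919-fold higher. The anchoring protein Akap2, the cGMP-dependent kinase Prkg2 and the chromatin protein Hmga2 were at least 1325-, 1076- and 967-fold higher. Spp1, which encodes osteopontin, had 2 counts in the control and 14905 and 7726 with sg1 and sg2, a pooled ratio of 5128 (95% counting interval 1419 to 42340). All 12 of these genes passed edgeR's test, with adjusted p between 1.64e-05 and 2.19e-05.

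The genes lower in the knock-out were examined next. Pkd2l1, a cation channel subunit (chromosome 19, 44147637 to 44248328), fell from 102 CPM to 0.681 ± 0.0399 CPM, 149-fold (log2 -7.22, SE 0.501, adjusted p = 1.64e-05). The potassium channel gene Kcnj3 fell 67.1-fold (20.3 to 0.302 ± 0.0201 CPM). The secreted antagonist Cer1 fell 67.0-fold (4151, 37 and 103 counts in control, sg1 and sg2; log2 -6.79 with sg1 and -5.53 with sg2) and Cntn4, a neuronal adhesion molecule, 67.4-fold (378, 9 and 3 counts; log2 -5.17 and -6.42). Tspan6, AW551984, Cib3, Acvr1c, Cdh18 and Myom2 fell between 42.7-fold and 26.3-fold, from control levels of 7.29 to 21.3 CPM; Tspan6 had log2 -6.39 with sg1 and -4.43 with sg2 (316, 2 and 15 counts). The long non-coding RNA Miat (chromosome 5, 112213228 to 112228948) was the most abundant of the 12 named lower genes. It fell from 579 CPM to 28.4 ± 1.96 CPM, 20.4-fold (log2 -4.35, SE 0.409, adjusted p = 4.38e-05). Itga4, an integrin subunit, fell 20.6-fold, from 136 CPM to 6.63 ± 0.665 CPM.

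**Figure D1:**
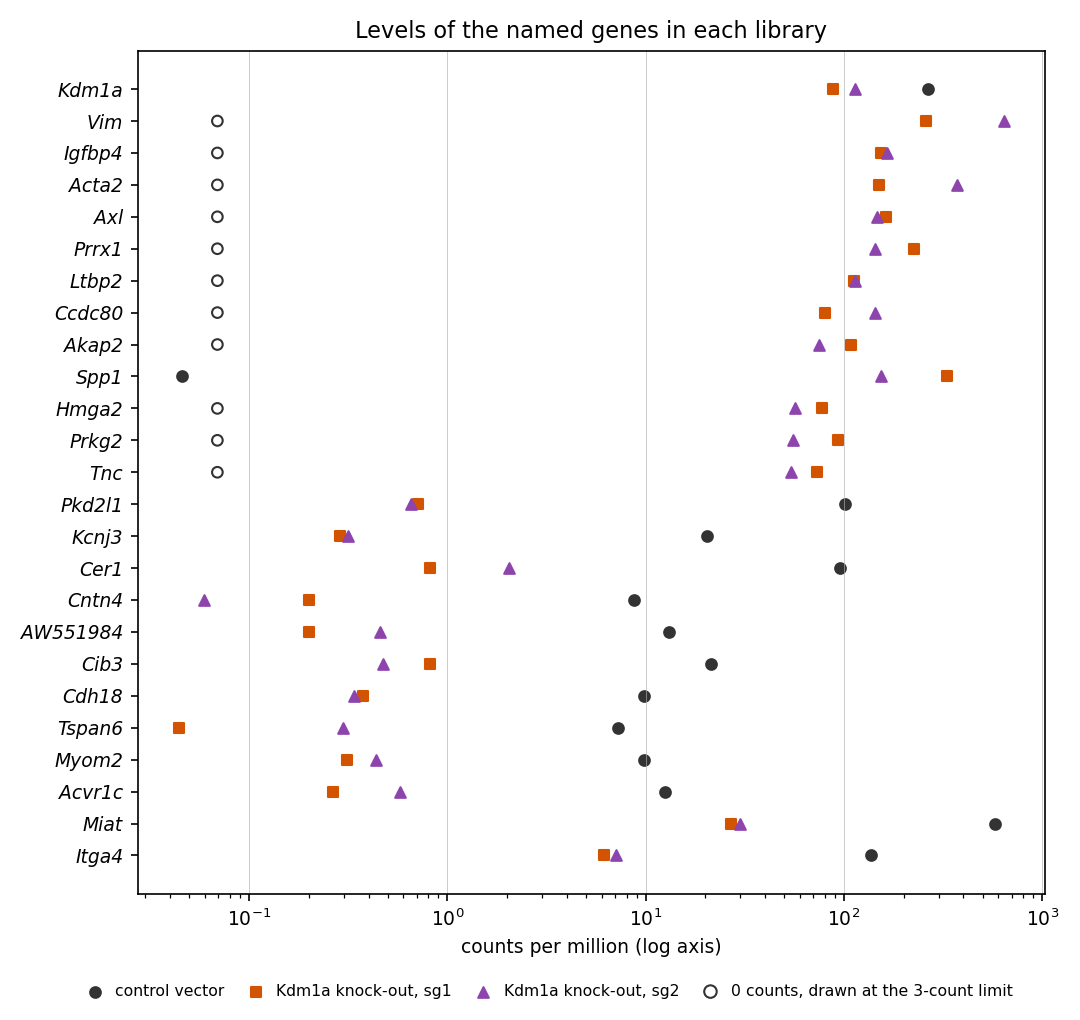
CPM (log axis) of Kdm1a and of the 12 higher and 12 lower named genes, with 1 symbol per library; open circles stand for 0 counts in the control, drawn at the limit of 3 counts. For each of the 24 named genes below Kdm1a, both guides lie on the same side of the control.

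In all, 1279 of 15936 genes tested passed edgeR's test at an adjusted p under 0.05, of which 1008 were higher and 271 lower in the knock-out, and 78.8% of the calls were thus increases. Each of the 1279 differed at least 1.5-fold from the control in the same direction with both guides. Of the higher genes, 261 had 0 counts in the control, so that no finite fold change can be given for them. The number of calls varied between analyses: limma-voom called 513 higher and 198 lower genes, and limma-trend on log2(RPKM + 1) called 27 and 4, where the measure, scaling, pseudocount and test all differ from edgeR's and were not told apart. Counts were also simulated with the spread of these libraries and 200 changed genes per run. In them edgeR recovered 3.58% of 2-fold, 36.7% of 4-fold and 81.2% of 16-fold changes. With so few changed genes the adjusted threshold is stricter than with the 1279 calls here. Recovery in these data may thus be higher and was not measured, and changes of moderate size may still have been missed.

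Gene lists fixed before the data were examined were then compared. The mesenchymal, YAP/TAZ and TGF-beta lists were higher in the knock-out. Of 19 tested mesenchymal genes, 13 rose and 0 fell, among them Sparc, a matrix glycoprotein (at least 858-fold; 59.4 ± 16 CPM), beside Vim and Acta2. Of 18 YAP/TAZ targets and partners, 12 rose and 0 fell. Axl is among them, Ankrd1 was at least 478-fold higher (33.0 ± 12.2 CPM), and Wwtr1, which encodes TAZ itself, had 1 count in the control and 2873 and 3509 with the guides, a pooled ratio of 2892 (counting interval 519 to 114200). Of 20 TGF-beta pathway genes, 9 rose and 0 fell. Ltbp2 is among these, and the ligand Tgfb1 rose 83.6-fold (61.7 ± 23.2 CPM). Adjusted over the list alone, 15, 13 and 10 members rose, and 0, 1 and 1 fell. The set test camera gave adjusted p of 3.48e-15, 1.5e-14 and 8.92e-05 with a preset correlation, and an adjusted p = 0.594 with an estimated correlation for each. Markers of fibroblasts moved with these lists: 5 of 8 tested rose, including Col1a1 (4, 10119 and 2752 counts in control, sg1 and sg2) and Pdgfrb (221-fold; 66.2 ± 24.1 CPM), and 6 rose adjusted over the list alone (camera adjusted p = 1.15e-08, and adjusted p = 0.594 with an estimated correlation). Col1a2, the partner chain of Col1a1, had 0, 15 and 6 counts.

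Genes typical of the non-neuroendocrine cells of SCLC were also higher. Of 24 tested members, 13 rose and 1 fell, with 17 and 1 adjusted over the list alone. Myof, a membrane repair protein, rose 589-fold (109 ± 48.9 CPM), Lgals3, which encodes galectin-3, 240.5-fold (44.4 ± 28.5 CPM), and the secreted YAP target Cyr61 108-fold (104.3 ± 43.6 CPM). Camera gave an adjusted p = 1.5e-14 with the preset correlation and an adjusted p = 0.594 with an estimated correlation. Slc16a5, a transporter of the monocarboxylate family, was the member that fell, 4.85-fold; it lies outside the naming rule and was chosen after its values were seen.

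Neuroendocrine and synaptic genes were lower. Of 33 tested neuroendocrine genes, 6 fell and 1 rose, and 15 fell and 1 rose adjusted over the list alone. The kinesin gene Kif1a fell 6.17-fold (299 to 48.4 ± 12.8 CPM), the synaptic vesicle protein Syn1 4.54-fold (64.7 to 14.3 ± 1.12 CPM) and the kinesin Kif5c 4.5-fold (243 to 53.9 ± 7.61 CPM). Calca, the calcitonin and CGRP precursor, was the member that rose, 3.66-fold (98.0 to 359 ± 180 CPM; adjusted p = 0.0476), and it was chosen after its values were seen. Its call was lost under 5 alternatives, with adjusted p from 0.00267 to 0.21 over all of them. Insm1, a transcription factor of neuroendocrine cells that was also chosen after its values were seen, did not pass the test (log2 -1.08, adjusted p = 0.147). Of 26 synapse and exocytosis genes, 6 fell and 0 rose, and 8 fell adjusted over the list alone. Sv2b, a vesicle glycoprotein, fell 13.3-fold (139 to 10.5 ± 3.57 CPM), the calcium channel gene Cacna1b 5.11-fold (69.1 to 13.5 ± 10.1 CPM; log2 -1.74 with sg1 and -3.42 with sg2) and the calcium sensor Syt1 5.05-fold (394 to 78.1 ± 43.1 CPM). The call of Cacna1b was lost under 3 alternatives, a mean count of at least 50, limma-trend and the length correction (adjusted p = 0.0601, 0.193 and 0.0572). Camera gave adjusted p of 1.18e-10 for the neuroendocrine and 1.18e-08 for the synapse list, and an adjusted p = 0.594 with an estimated correlation for both. Long genes were lower with sg2 as a whole: in the 3187 longest genes the median log2 fold change was -0.11 with sg1 and -0.45 with sg2. With that length trend removed, an alternative added after the data were seen, 5 neuroendocrine and 6 synapse genes fell.

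Interferon-response and antigen-presentation genes were higher. Of 27 interferon-response genes, 14 rose and 0 fell, and 20 rose adjusted over the list alone. Cxcl10, an interferon-induced chemokine, had 0 counts in the control and was at least 160-fold higher (11.1 ± 4.08 CPM). The guanylate-binding protein gene Gbp2 had 2, 697 and 1447 counts in control, sg1 and sg2, a pooled ratio of 486 (counting interval 134 to 4014), and Oasl2 2, 991 and 914, a ratio of 432 (119 to 3567). Of 19 genes of MHC class I and antigen presentation, 11 rose and 0 fell, the same number as adjusted over the list alone. The class I transactivator Nlrc5 rose 34.2-fold (13.4 ± 4.89 CPM) and the immunoproteasome subunit gene Psmb8 38.2-fold (68.8 ± 53.7 CPM). B2m, the light chain of class I, rose from 12.3 to 265 ± 147 CPM, 21.6-fold. H2-Q4 rose 48.6-fold (33.6 ± 19.7 CPM), but class I genes have near-identical copies and reads shared between them could not be told apart. Camera gave adjusted p of 3.41e-16 and 2.15e-09 for these lists, and an adjusted p = 0.594 with an estimated correlation for both.

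Among 10 regulators of SCLC subtypes and Myc genes, 3 rose and 1 fell, the same numbers as adjusted over the list alone. Pou2f3, a tuft cell factor, had 0, 30 and 116 counts in control, sg1 and sg2. The mean of both guides was at least 21.4-fold higher, a call lost with limma-voom, limma-trend and the length correction. Myc rose 8.47-fold (4.50 to 38.1 ± 2.72 CPM), Yap1 7.06-fold (11.3 to 79.6 ± 24.1 CPM), and Neurod1 fell 5.21-fold (66.6 to 12.8 ± 0.805 CPM). Of 25 Notch pathway genes 7 rose and 1 fell, with 8 and 5 adjusted over the list alone. Rest, a repressor of neuronal genes, rose 49.4-fold (0.323 to 16 ± 0.0777 CPM), Notch1 37.7-fold and the Notch target Hes1 9.88-fold (9.68 to 95.7 ± 46.8 CPM), and Heyl had 0, 82 and 46 counts, its call also lost in those 3 settings. The ligand Dll1, chosen after its values were seen, was the member that fell, 5.18-fold. Camera gave adjusted p of 0.70 and 0.582 for these lists, so neither list passed, and in both the mean log2 fold change (0.18 and 0.71) lay above the median (-0.55 and 0.05); camera's direction for the regulators was down. In the CoREST list Snai1, an inducer of epithelial-mesenchymal transition, rose 31.7-fold (0.392 to 12.4 ± 5 CPM) and 14 of 15 members did not pass. The list as a whole leaned down, with 12 of 15 members below the control with both guides and median log2 fold changes of -0.33 with sg1 and -0.66 with sg2, but missed the threshold (camera adjusted p = 0.0599). Among 18 epithelial genes, Krt19 rose 38.7-fold (28, 739 and 1700 counts in control, sg1 and sg2) and Dsp fell 2.78-fold (373 to 134 ± 16.9 CPM; adjusted p = 0.0387), and the list leaned down without passing (camera adjusted p = 0.0868). The call of Dsp was lost under 5 alternatives (adjusted p up to 0.159), and its log2 fold change was -0.94 instead of -1.47 with the length trend removed.

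Of 25 cell cycle and 20 cholesterol synthesis genes, 0 passed edgeR's test (camera adjusted p = 0.962 and 0.0677), with 0 and 1 at an unadjusted p under 0.05, and 0 passed with DESeq2, limma-voom or limma-trend. Among the largest fold changes in them were those of Ccne2 (log2 -0.90, adjusted p = 0.389) and Aurka (log2 0.89, adjusted p = 0.368) in the cell cycle list, and Hmgcs1 (log2 -0.75, adjusted p = 0.382) in the cholesterol list. Fas, a death receptor, was the member of 21 apoptosis regulators that passed (0, 114 and 189 counts), and Pfkm, a phosphofructokinase, the member of 19 glycolysis genes (4.95-fold higher). The camera adjusted p of these lists were 0.93 and 0.552. Genes of other cell types of the lung were also tested. Sftpb, a surfactant protein, rose 238-fold (21.9 ± 5.54 CPM), Sftpa1 had 0, 141 and 66 counts, and the club cell gene Cyp2f2 had 37, 0 and 0, giving 2 of 12 alveolar and club genes called higher and 1 lower, with 10 of 12 above the control with both guides (camera direction up, adjusted p = 0.0292, and adjusted p = 0.594 with an estimated correlation). The call of Sftpa1 was lost with limma-voom and limma-trend, and that of Cyp2f2 with upper-quartile factors, limma-trend and the length correction. Kdr rose 81.7-fold (16.9 ± 10.4 CPM), the sole call among 4 endothelial genes, and Sox9 (at least 131-fold) and Pou2f3 were the calls among 7 tuft genes. The camera adjusted p were 0.107 and 0.234. Of 11 immune markers 2 were testable, Cd68 (log2 0.76, adjusted p = 0.636) and Cd79a (log2 0.56, adjusted p = 0.908), and the list had a camera adjusted p = 0.753. Neither had an unadjusted p under 0.05 with edgeR, and 0 of the 2 passed with DESeq2, limma-voom or limma-trend.

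**Figure D2:**
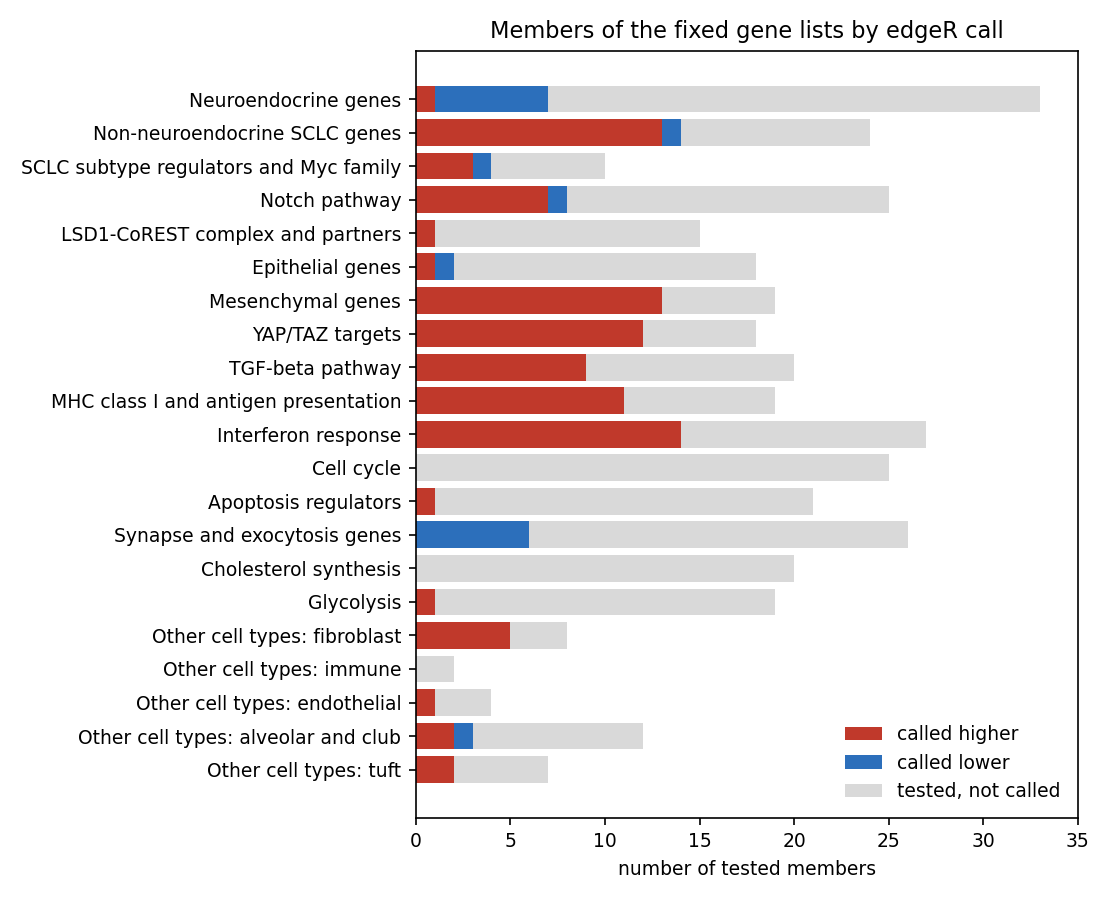
Number of tested members of each fixed gene list called higher, called lower or not called in the Kdm1a knock-out by edgeR, as stacked bars. The interferon list has 14 higher members of 27 and the neuroendocrine list 6 lower and 1 higher of 33.

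The guides were then compared with each other, as a measure of the spread within the knock-out. Their fold changes over the control moved together across genes, with a Pearson correlation of 0.862 and a Spearman correlation of 0.773. Unchanged libraries simulated against the shared control gave 0.502 and 0.472 on average over 50 simulations, and genes are not independent replicates. The covariance was 2.6 against a simulated 0.376, and 79.0% of genes had the same sign against 66.7%. At least 1.5-fold higher with both guides were 2915 genes, against 1693 in the simulations and 1082 for independent lists of 3711 genes with sg1 and 4647 with sg2. At least 1.5-fold lower with both were 2031 genes, against 1441 and 667 from lists of 2482 and 4280. With 1 control library the control cannot be split, so part of the excess may come from it.

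The guides also differed. At least 1.5-fold apart were 6155 genes (38.6% of those tested), 3445 higher with sg1 and 2710 higher with sg2, and 222 genes were at least 1.5-fold from the control in opposite directions. Hoxd13, a posterior homeobox gene, had 0 counts in the control, 1 with sg1 and 3538 with sg2. Msn, which encodes moesin, was 97.1-fold, Mrvi1 94.2-fold, the cyclin gene Ccnd2 29.1-fold and Clu, which encodes clusterin, 24.3-fold higher with sg2 than with sg1. Clu reached 985.5 CPM with sg2 and 40.5 CPM with sg1, against 7 counts in the control. In the other direction Trim66 was 12.1-fold, Bpifa1, a secreted airway protein, 11.6-fold, the cadherin Cdh11 10.9-fold, Deptor 10.8-fold and Serpinf1 10.1-fold higher with sg1. Trim66 (16.81, 25.65 and 2.116 CPM in control, sg1 and sg2) and Deptor (13, 23.44 and 2.175 CPM) lay below the control with sg2. Bpifa1, Cdh11 and Serpinf1 had 0, 13 and 40 counts in the control and lay above it with both guides. The comparisons of these 10 genes between the guides rest on single libraries and have no replicate check. The sg1 and sg2 counts differed more than repeat deposits of 1 library would (chi-square over degrees of freedom of 196).

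**Figure D3:**
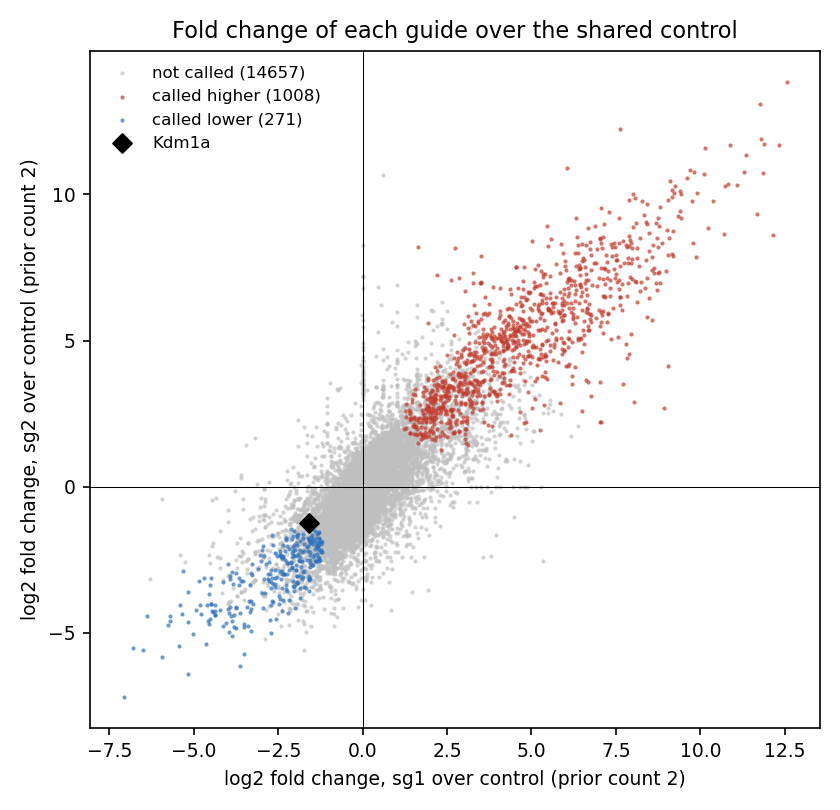
Log2 fold change over the control with sg1 (horizontal) and sg2 (vertical), 1 point per tested gene, coloured by edgeR call, with Kdm1a as a diamond. The called genes, 1008 higher and 271 lower, lie in the upper right and lower left.

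The authors' deposited lists of genes changed with both guides were compared last; the authors chose them on these same libraries, so the overlap is no independent evidence. The authors' deposited table listed 1833 genes as up and 2154 as down. Of these, 1789 (97.6%) and 1477 (68.6%) were also at least 1.5-fold changed in the same direction with both guides here, and 794 (43.3%) and 252 (11.7%) passed edgeR's test. Conversely 78.8% of the higher and 93.0% of the lower calls were on the authors' lists. The up list equalled the set of genes with RPKM above 1 and over 1.5 times the control with both guides, and the down list those with a control RPKM above 1 and less than 0.75 of the control with both. A cut at the inverse of 1.5 would have kept 1486 of the 2154 down genes.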

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

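Results were recomputed under 1 alternative at a time; the DESeq2 Wald test also takes DESeq2 size factors and left 927 genes without an adjusted p, limma-trend on log2(RPKM + 1) changes measure, scaling, pseudocount and test together, and the gene-length correction and the fit without chromosome 15 were chosen after seeing the data. Limma-voom called 513 higher genes, and limma-trend on log2(RPKM + 1) called 27 higher and 4 lower; which of the changed choices did this was not tested. Lower genes were 511 without the count filter and 180 at a mean count of at least 50, where fewer genes were tested. Calls from other settings lay within 1.5 times the 1008 higher and 271 lower genes, and all 1279 calls were shared with DESeq2 size factors and 948 with the length correction.

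Kdm1a passed the threshold with DESeq2 size factors (-1.41), without the filter (-1.39), with the DESeq2 Wald test (-1.41) and with the length correction (-1.48); its adjusted p ranged from 0.0166 to 0.127 over the alternatives. With either guide left out, its log2 fold change lay between -1.60 and -1.23. With log2(RPKM + 1), 1722 genes were higher and 1204 lower with both guides and 3463 were apart between guides, and at a fold of 2 the lower and apart counts were 1040 and 2965. With a single guide the higher count was 3711 to 4647 and the lower count 2482 to 4280. The set test with an estimated correlation passed 0 lists, where the smallest unadjusted p was 0.0663, and fry passed 0, with 5 at an unadjusted p under 0.05; both rest on 1 residual degree of freedom. With the length correction 12 lists passed, the CoREST (adjusted p = 0.037) and cholesterol lists (0.0201), both downward, being the additions.

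Of 76 named genes followed, 68 were called; none changed sign under the settings with a test, and limma-trend on log2(RPKM + 1) ended 55 calls. The guides' correlation was 0.899 at a mean count of at least 50 and 0.859 with a prior count of 10. Calca, Dsp, Pou2f3, Heyl, Cacna1b, Col3a1, Sftpa1 and Cyp2f2 each lost their call in at least 1 setting besides the RPKM one. Depth limits genes with 0 control counts to a lower bound of the fold, and those with 1 to 3 to a wide interval. No paired analysis was possible because there was 1 control library and the sample titles name no pairs.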

Other observations

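The tests of fibroblast content, of a common fall of neuroendocrine genes, of rare cells in the control and of gene length were chosen after the results were seen, as were the gene families. Families of genes sharing a symbol stem were compared among 267 stems with at least 8 tested members, by a hypergeometric test against all tested genes. Interferon-inducible Ifi genes held 8 higher of 12 (adjusted p = 2.62e-05), among them Ifi44, Ifi47 and Ifi204. Collagens held 13 higher of 38 (3.93e-05), including Col5a1, Col6a1 and Col12a1, and 1 lower, Col8a1. Guanylate-binding Gbp genes held 5 of 8 (0.00425), the Cxcl chemokines 5 of 10 (0.0129), Tnfrsf receptors 6 of 17 (0.0208), interleukin genes and receptors 9 of 38 (0.0208) and carbonic anhydrases 5 of 12 (0.0208). Cadherins held 4 lower of 17 (0.0437), Cdh8, Cdh9, Cdh18 and Cdh23, and 1 higher, Cdh11. With upper-quartile factors the counts were 7, 12, 4, 5, 6, 8, 4 and 3 in that order, and no called member changed sign with either other scaling. Members of a family can share reads.

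Mesenchymal genes absent from the control were abundant with both guides. An admixture of ordinary fibroblasts is argued against by collagen: Col1a2 reached 0.148% of the Col1a1 count with sg1 and 0.218% with sg2 (95% counting interval 0.0799 to 0.475%), while cells that build type I collagen from both chains hold both mRNAs. Dilution of unchanged neuroendocrine cells by another population stays open: it would lower their genes by 1 factor, and 2 of 33 neuroendocrine genes, Calca and Resp18, left the list's median by over 2 standard errors, both above it, with the control assumed to vary like the guides. This standard error was set after the outcome was seen; taking the control as free of error, as was done first, 9 of 33 left. Rare cells already in the control may have grown out: 0 counts of Vim there allow up to 0.0267% of the sg1 level and 0.0108% of the sg2 level. Such outgrowth cannot be told apart from a change in the cells, because each library pools all cells and rarer ones would escape its counts. An effect of Kdm1a loss stays open, as untested.

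Genes of chromosome 15 were higher with both guides. Among 389 genes with a mean count of at least 500 the median log2 fold change was 0.31 with sg1 and 0.26 with sg2, against -0.12 to 0.12 and -0.15 to 0.21 for the other autosomes. Without called genes, 365 genes were left, with medians of 0.26 with sg1 and 0.21 with sg2. The other autosomes then reached 0.07 and 0.18 at most. A median over so many genes hardly responds to a few strongly induced ones, so this removal does not test them as a cause. Extra copies of the whole chromosome would raise its parts alike: 73.7% of its windows of 20 genes had medians above 0 with both guides, against 61.1% for the highest other autosome, between the limits set beforehand, so this cannot be told apart from a regional change. Chromosome X had medians of -0.18 and -0.26, and Xist, chosen after its values were seen, had 115858, 42575 and 37534 counts in control, sg1 and sg2 (adjusted p = 0.0106).

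The guides were at least 1.5-fold apart in 6155 genes. Gene length followed the difference (Spearman 0.316 across genes, which are not independent replicates), but removing the trend left 5400 genes apart, so length is argued against as the whole cause. Of 8398 genes with a mean count of at least 1000 over the 3 libraries, 26.9% were apart. That mean includes the control, so some of them had few counts with the guides, such as Cer1 with 37 and 103. Counting error is far below 1.5-fold where both guides hold such high counts. It is argued against as the whole cause for those genes only, and how many they are was not measured. Separately infected cultures may differ by more than counting error in any case, so the 26.9% does not tell the other causes apart. Differences between the edited populations or between library preparations may remain, and the design holds no test of them. The calls were then compared between splits of the libraries. With a guide as the lone library, the control is grouped with the other guide. Any difference between the control and that guide then widens the spread, so few calls there follow from the grouping itself. Of the 3 splits that take 1 library as the lone one, the real split called 1279 genes with edgeR (2912 at an unadjusted p under 0.05) and the highest other 0 (57 and 879 unadjusted); 3 splits are too few for a share under 0.05.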
